A study of Homo sapiens with 12 samples.

How the data were processed

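RNA sequencing libraries of U2OS cells were analysed in 4 groups of 3, namely input and Cap IP of cells with eIF4E-Flag and of cells with the vector. The deposited values are read counts per gene name, with no normalization. According to the submitters' processing notes, reads were aligned with STAR 2.5.1b to GRCh38.p5 and counted with featureCounts 1.4.5-p1, and DESeq2 was used. Per the labels, libraries were made with KAPA RNA HyperPrep with RiboErase, a stranded kit, and sequenced as 75-cycle single-end reads. The strand setting of the counting and the gene annotation are not given in the sources used here. The raw reads were not analysed here.

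Libraries held 1206321 to 1813486 counts. Genes with at least 1 count numbered 22052 to 25950 in input libraries and 18002 to 20381 in Cap IP libraries. A floor of 3 counts stood for 1.65 to 2.49 CPM (counts scaled to library size). TMM factors lay between 1.17 and 1.49 in input and between 0.667 and 0.891 in Cap IP. Of all 58684 genes, 24985 had no counts in any library. No 2 replicates were copies of each other, with a chi-square per degree of freedom between 5.98 and 23.0 in each pair of replicates, where technical copies would give about 1.

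Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by filterByExpr, which left 12460. They were scaled with TMM and fitted with edgeR's quasi-likelihood model with a mean for each of the 4 groups over all 12 libraries. The common dispersion was 0.0883. There were 5 comparisons. They were eIF4E against vector in input, Cap IP against input in vector cells, Cap IP against input in eIF4E cells, the difference of these last, and eIF4E against vector in Cap IP. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are the log2 values of edgeR's fit. A prior count of 2 entered the log2 CPM used for correlations, principal components and overlap of groups. Where a group had 0 counts, the fold is a bound against 3 counts over the group, and with 1 to 3 counts it is a ratio with a 95% counting interval.

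The comparisons, the 34 lists of genes and the alternatives were fixed before the data were examined, except where the closing section says otherwise. The genes named were EIF4E and the cap synthesis enzymes, then the 8 genes with the largest change in each direction. Those had to pass, with an average log2 CPM of at least 2, a symbol that is no clone name, groups without overlap and 1 member per family of copies. Where fewer than 8 passed, those with the smallest p were added as values that did not pass. In each list described, up to 4 members with the smallest p could be named. Members named beyond these, such as those that passed adjusted over a list alone, were chosen after their values were seen. A few genes that this rule names are not reported here.

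Lists were tested with camera at an inter-gene correlation of 0.01, with an estimated correlation, and with fry, adjusted over the lists of a comparison. Lists with under 5 tested members were given as values. RNA classes and the anchor on the 13 mitochondrial mRNAs used the log2 Cap IP over input per culture, with a pseudocount of 2 CPM, and an exact permutation test of 3 against 3 cultures, whose smallest two-sided p is 0.1.

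Gene classes, positions and opposite-strand exons were taken from GENCODE release 44. By symbol 33465 genes matched, with 57.0% of the counts, and by an older symbol 1602 with 4.24%. The remaining 23617 genes with 38.8% were not matched. Exons opposite to another gene were found for 8831 matched genes. These steps and the figures used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.

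Titles of input and Cap IP libraries share a stem, and titles of vector and eIF4E libraries share a tag. A stem is called a culture here, although the labels do not say that it marks a separate culture. Whether these pair the libraries was checked by correlating the residuals from the group means. For the culture stem these correlations were 0.43, 0.27 and 0.44 in vector cells and 0.35, 0.08 and 0.11 in eIF4E cells. For the tag they were 0.18, 0.01 and -0.04 in input and 0.20, 0.16 and 0.30 in Cap IP. The count with the tag as a block is therefore given beside the count without it for eIF4E against vector in Cap IP.

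Alternatives tried were DESeq2 1.42.0 as the test, DESeq2 size factors, total counts or mitochondrial mRNAs as library sizes, and library sizes without the 20 most abundant genes. Others were no filter on low counts, a filter of 50 counts in 3 libraries, only the groups compared, blocks for the culture and the tag, and each library left out in turn. The procedure was tested on simulated data with 200 changed genes among 12460 per comparison, 100 at 2-fold and 100 at 4-fold. Of those at 4-fold it called 67% in input, 63% and 66% for Cap IP against input in vector and eIF4E cells, 18% for the difference and 50% in Cap IP. False calls numbered between 1 and 10 per comparison. In the real Cap IP against input comparisons far more than 200 genes were called, so the shares of 63% and 66% do not apply to them.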

Results

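RNA sequencing was carried out on U2OS cells, a human osteosarcoma line, that stably carried either eIF4E-Flag or the vector alone. eIF4E is the translation initiation factor that binds the m7G cap at the start of mRNAs. Total RNA (input) and RNA from a cap immunoprecipitation (Cap IP) were sequenced from each kind of cell, with 3 libraries in each of 4 groups and 12 libraries in all. The series title puts the question whether eIF4E changes how much of each transcript, coding or noncoding, carries an m7G cap. The deposited values were counts per gene. The vector input libraries held 1279340, 1484732 and 1813486 counts, and the eIF4E input libraries 1743397, 1491450 and 1672507. The vector Cap IP libraries held 1385397, 1442097 and 1786940 counts, and the eIF4E Cap IP libraries 1420138, 1474341 and 1206321. Of 58684 genes in the file, 12460 had enough counts to be tested. The labels do not say whether the replicates are separate cultures, so the p-values measure only the spread between these samples. The word culture stands below for the input and Cap IP libraries that share a title stem.

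Libraries of 1 group resembled each other more than input resembled Cap IP. Pearson correlations of log2 CPM (counts scaled to library size) lay between 0.893 and 0.942 within groups and between 0.687 and 0.791 across input and Cap IP. The first principal component, which parted all Cap IP libraries from all input libraries, held 58.5% of the variance. The counts of a gene and of a gene on the opposite strand over the same exons were often far apart. VIM-AS1, opposite to the intermediate filament gene VIM, held a mean of 17369 counts per library against 1289 for VIM. BEST1, opposite to the ferritin heavy chain gene FTH1, held 23099 against 548 for FTH1. The strand setting of the counting is not given in the sources used here. For genes with exons opposite to another gene, which hold 39.3% of all counts, the RNA behind the counts is therefore uncertain, and the opposite gene is named for many of those described here. MT-ND6, which is encoded on the other mitochondrial strand than the rest of the mitochondrial mRNAs, held a mean of 6805 counts against 1304 for MT-CO1. Genes without such exons, the mitochondrial mRNAs among them, are thus not free of the same doubt.

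EIF4E itself, on chromosome 4 at 98879276 to 98929133 of GRCh38, had few counts in every library. The vector input libraries held 15, 9 and 15 counts for EIF4E, or 9.70, 4.81 and 6.32 CPM. The eIF4E input libraries held 39, 27 and 23, or 15.4, 13.2 and 11.9 CPM. In Cap IP, EIF4E had 15, 12 and 30 counts in vector cells and 29, 26 and 27 in eIF4E cells. In CPM these were 14.6, 12.6 and 19.2 in vector cells and 29.8, 25.1 and 26.8 in eIF4E cells. EIF4E was higher in the 3 eIF4E input libraries than in the 3 vector input libraries, by 0.98 ± 0.36 (SE) on the log2 scale, and this did not pass over all genes in edgeR's quasi-likelihood test (Benjamini-Hochberg adjusted p = 0.231). In Cap IP it was higher by 0.79 ± 0.35 (edgeR adjusted p = 0.492). EIF4E has exons opposite to another gene, so which RNA these counts hold is uncertain, and they are a weak check of the labels.

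**Figure D1:**
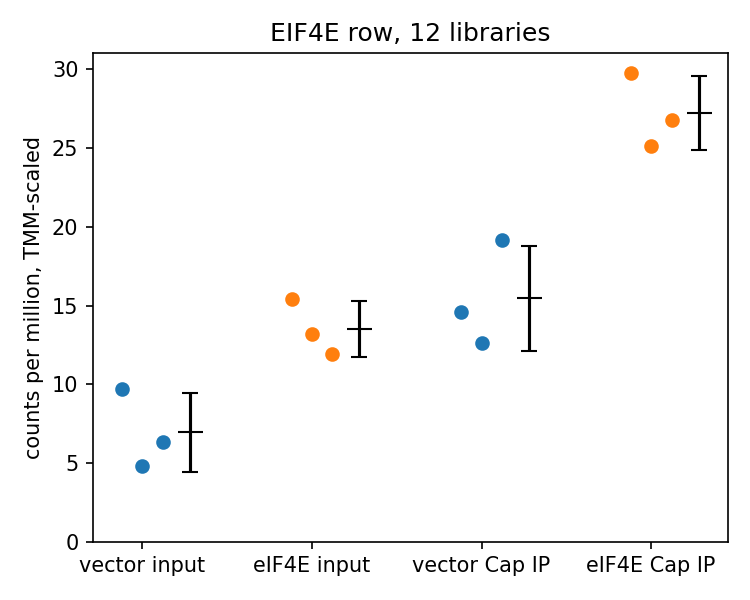
CPM (TMM-scaled, linear axis) of EIF4E in each of the 12 libraries, as points by group, with the mean and SD of the 3 libraries of each group beside them. The group means were 6.94 in vector input, 13.5 in eIF4E input, 15.4 in vector Cap IP and 27.2 in eIF4E Cap IP, with no overlap between eIF4E and vector within either fraction.

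None of the tested enzymes that make the cap passed between eIF4E and vector input. CMTR1, which methylates the first transcribed nucleotide and lies on chromosome 6 at 37433219 to 37482827, changed by -0.45 ± 0.33 (edgeR adjusted p = 0.577). RNMT, the cap methyltransferase, opposite to FAM210A, changed by 0.36 ± 0.48 (edgeR adjusted p = 0.778), and FAM103A1 (RAMAC), its activating subunit, opposite to C15orf40, by 0.10 ± 0.41 (edgeR adjusted p = 0.940). PCIF1, which methylates a first adenosine, changed by 0.06 ± 0.30 (edgeR adjusted p = 0.947). RNGTT, the capping enzyme, and CMTR2 held 62 and 53 counts over all 12 libraries and were not tested. In the self-test, 16% of simulated changes of 2-fold and 67% of those of 4-fold were called in the input comparison.

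The first comparison asked which total RNA levels differed between eIF4E and vector cells. CDR1, a brain-associated gene on the X chromosome (140783578 to 140784366), was among the genes that fell in eIF4E input. Genes for the crosslinking enzyme TGM2, the epithelial keratin KRT15, complement component C3 and the survival factor BCL2L1 rose. Genes for the cancer-testis antigen PAGE2B, the ion channel TRPA1 and the long noncoding RNA HOTAIR fell. As groups, spliceosome and p53 target genes lay slightly above the other genes by camera with its preset correlation, and none of their members passed over all genes. With an estimated correlation neither list passed (adjusted p = 0.461 and 0.124).

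CDR1, whose exon lies opposite to LINC00632, fell from 673 ± 204 to 111 ± 22.6 CPM (SD, n = 3 each), a log2 change of -2.60 ± 0.29 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 1.19e-04). TGM2, on chromosome 20 at 38127385 to 38166578 and opposite to RPRD1B, rose from 33.4 ± 21.7 to 406 ± 213 CPM, by 3.58 ± 0.57 (edgeR adjusted p = 0.00598). KRT15, on chromosome 17, rose by 3.86 ± 0.66 (edgeR adjusted p = 0.0118). BCL2L1, on chromosome 20 at 31664452 to 31723989, encodes BCL-XL, is on the list of reported eIF4E targets and lies opposite to ABALON. It rose from 55.0 ± 5.77 to 169 ± 51.7 CPM, by 1.62 ± 0.32 (edgeR adjusted p = 0.0299). ABALON held a mean of 3537 counts per library against 149 for BCL2L1. It stood at 1.10 ± 0.33 in input and did not pass (edgeR adjusted p = 0.143), so a rise of BCL2L1 mRNA is uncertain. C3 rose by 3.21, the tight junction gene CGN by 1.78 and FAM129B, an antiapoptotic scaffold gene, by 1.62. The pseudogenes RPL13AP20 and IMPDH1P4 rose by 3.13 and 1.79, and their reads could not be separated from those of near-identical copies.

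Among the genes that fell in input, SEMA6A-AS1, opposite to the semaphorin gene SEMA6A, fell by 3.79 ± 0.61 on the log2 scale (edgeR adjusted p = 0.00598), and PALM3, a paralemmin gene, fell by 3.76 ± 0.65 (edgeR adjusted p = 0.0118). TRPA1, opposite to MSC-AS1, fell by 3.39, and the sodium-glucose cotransporter gene SLC5A9 fell by 2.95. The eIF4E input means of PALM3 and TRPA1, 0.93 and 1.67 CPM, lay near or below the level of 3 counts per library, so these sizes are uncertain. PKIB, an inhibitor of protein kinase A, fell by 2.73, PAGE2B fell by 2.68 and RNF150, a RING finger gene, fell by 2.62. HOTAIR fell by 2.54 ± 0.56 (edgeR adjusted p = 0.0419). Without any 1 of the 6 libraries, CDR1 and TGM2 were called each time, with edgeR adjusted p of at most 0.00520 for CDR1 and 0.0449 for TGM2. BCL2L1 had an adjusted p of 0.0722 without vector input replicate 1, 0.151 without replicate 3, 0.183 without eIF4E input replicate 2 and 0.136 without replicate 3. For HOTAIR the values without the same 4 libraries were 0.143, 0.142, 0.235 and 0.183. Of the 16 genes with the largest changes, 10 were called without vector input replicate 1, 13 without replicate 2 and 6 without replicate 3. They were 14 without eIF4E input replicate 1, 3 without replicate 2 and 2 without replicate 3.

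In all, 66 genes passed an adjusted p of 0.05 in input by edgeR, 13 higher and 53 lower in eIF4E cells, of 12460 tested. At an unadjusted p under 0.05 there were 1683 genes, and DESeq2 called 137, which included 63 of the 66. Of the 66 genes, 30 had exons opposite to another gene, 15 had none and 21 carried names that the annotation did not match. In 18.7% of all genes the 3 eIF4E libraries did not overlap the 3 vector libraries, where chance gives 10%. The count rested on single libraries. It was 7 without eIF4E input replicate 2, 9 without replicate 3, 109 without replicate 1 and 13 without vector input replicate 3.

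Of the 34 lists of genes fixed before the data were examined, 8 lay above the other genes in input by camera with its preset correlation of 0.01, and none of these calls held with an estimated correlation. The median log2 change of the 31 spliceosome genes was 0.40 (camera adjusted p = 1.74e-04, and adjusted p = 0.461 with an estimated correlation), with 27 of 31 positive. No spliceosome gene passed, over all genes or adjusted over the list alone, and the smallest p belonged to the helicase gene DHX16 at 0.72 and the U5 factor gene EFTUD2 at 0.87. The 22 p53 target genes had a median of 0.51 (camera adjusted p = 1.74e-04, and adjusted p = 0.124 with an estimated correlation). Of them 0 passed over all genes and 3 rose adjusted over the list alone, the glycolysis regulator TIGAR (edgeR adjusted p = 0.104 over all genes), the stress cytokine gene GDF15 at 2.08 and FDXR at 1.00. The 8 NF-kB genes had a median of 0.97 (camera adjusted p = 0.00956, and adjusted p = 0.461 with an estimated correlation), with NFKB2 at 1.09 passing adjusted over the list alone. The 18 cholesterol synthesis genes had a median of 0.66 and FDPS 0.86 (camera adjusted p = 0.00956, and adjusted p = 0.510 with an estimated correlation). Medians were 0.46 for 24 hypoxia and glycolysis genes (camera adjusted p = 0.00477), 0.32 for 21 RNA polymerase II genes (0.00956), 0.30 for 24 MYC targets (0.0186) and 0.19 for 86 TOP mRNAs (0.0186). With an estimated correlation the adjusted p was 0.461 for hypoxia and for polymerase II, 0.602 for MYC targets and 0.761 for TOP mRNAs. TOP mRNAs encode ribosomal proteins and elongation factors and start with a terminal oligopyrimidine tract.

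The 26 reported eIF4E export or translation targets had a median of 0.20 in input (camera adjusted p = 0.110), and BCL2L1 was their 1 member called, over all genes and adjusted over the list alone. MYC, another of them, stood at 1.02 (edgeR adjusted p = 0.169). The 32 extracellular matrix genes had a median of -0.33 (camera adjusted p = 0.0704), and 0 passed over all genes. Among the members that passed adjusted over the list alone were the collagen genes COL3A1 at -2.40 and COL5A2 at -1.70. Others that passed adjusted over their lists alone included the interferon genes ISG15 at 2.09 and OAS3 at 1.77, and FOSL1 at 1.05 and MYC among immediate early genes. ISG15 and MYC have exons opposite to another gene. Medians of the other lists that did not pass ran from -0.28 to 0.41. They were 0.03 for cap-binding proteins, 0.26 for decapping, 0.17 for intron-encoded snoRNAs, 0.01 for long noncoding RNAs, 0.41 for snoRNA hosts, 0.22 for S phase, 0.04 for G2/M, 0.18 for interferon genes and 0.21 for ATF4 targets. They were 0.14 for immediate early genes, 0.07 for Wnt targets, 0.21 for nuclear respiratory chain genes, 0.29 for nuclear pore genes, 0.07 for cleavage and polyadenylation and 0.31 for epithelial markers. Medians were -0.21 for mitochondrial mRNAs, -0.28 for uncapped small RNAs, -0.17 for histones, -0.20 for osteoblast genes and -0.18 for KRAB zinc fingers, and each of these turned positive with library sizes from mitochondrial mRNAs. Lists with under 5 tested members were given no set test. The 4 trimethylguanosine-capped RNAs had a median of -0.79, the 3 neuronal markers -0.17 and the 1 tested blood marker, CORO1A, -0.26.

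The second comparison asked which RNAs the Cap IP took up relative to input in vector cells. Transcripts of RNA polymerase III, which carry no m7G cap, were lowest in Cap IP, and among single genes PRPF8, a splicing factor gene, and the translation factor genes EIF4G1 and LARP1 were lower. By camera with its preset correlation, intron-encoded snoRNAs, mitochondrial mRNAs and extracellular matrix genes were lower as lists. Replication-dependent histones were higher, and so were TOP mRNAs, whose median turned to -0.13 with total counts as library sizes. With an estimated correlation these 5 list calls were lost (adjusted p = 0.687 for snoRNAs and matrix genes and 0.896 for the others).

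RN7SL1, the RNA of the signal recognition particle, fell from 2301 ± 1355 CPM in vector input to 3.50 ± 2.56 in vector Cap IP, a log2 change of -9.45 ± 0.61 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 9.14e-09). RN7SK, a regulator of transcription elongation on chromosome 6, went from 3057 to 8.25 CPM, a log2 change of -8.38 ± 0.57 (edgeR adjusted p = 9.94e-09). RMRP, the RNA of RNase MRP on chromosome 9, fell by 8.28 ± 0.57 (edgeR adjusted p = 9.94e-09), and RPPH1, the RNA of RNase P, fell by 6.79 ± 0.48 (edgeR adjusted p = 1.06e-08). RN7SL5P had 249 counts in vector input and 0 in vector Cap IP, so that it was at least 50.8-fold lower against a floor of 3 counts over the group. Such bounds, and the intervals given below, cover counting error alone. On the same floor MIR3609 was at least 15.7-fold lower, PRKCA-AS1 at least 15.3-fold, and the pseudogenes GAPDHP61 and RPL3P6 at least 16.1-fold and 15.9-fold. Among snoRNAs and scaRNAs, which guide RNA modification, SNORA73B fell by 3.21 and SCARNA2 by 2.40. SCARNA10 had 155 counts in input and 1 in Cap IP, a log2 ratio of -6.57 (95% counting interval -11.9 to -4.07). SNORD3A, the U3 RNA with a trimethylguanosine cap, fell by 4.23, and RNU12 fell by 1.90.

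The genes with the largest gains in vector Cap IP all had exons opposite to another gene. TAF5, a subunit gene of transcription factor TFIID on chromosome 10 at 103367966 to 103389065 and opposite to ATP5MK, rose from 59.7 ± 25.2 to 762 ± 450 CPM, by 3.68 ± 0.55 (edgeR adjusted p = 4.86e-05). MCMDC2, a meiosis gene opposite to the snoRNA host SNHG6, rose by 3.60 ± 0.51 (edgeR adjusted p = 2.80e-05). TEX9, a testis gene opposite to MNS1 and RFX7, rose by 3.25. SSB, the gene of the La protein, opposite to METTL5, rose by 3.22, and FAM175A, a DNA repair gene opposite to MRPS18C, rose from 107 to 854 CPM. TAPT1-AS1, opposite to RPS21P4, rose by 3.09, the neuropilin gene NRP2, opposite to an unnamed gene, by 2.99 and the sulfotransferase gene SULT6B1, opposite to CEBPZOS, by 2.97. The vector input means of TAPT1-AS1, NRP2 and SULT6B1 were 1.45, 1.28 and 1.42 CPM. They lay near or below the level of 3 counts per library, so the sizes of these gains are uncertain. All 16 genes with the largest changes were called without any 1 of the 6 libraries. EIF4E was higher in vector Cap IP than in vector input by 1.19 ± 0.37 (edgeR adjusted p = 0.0163). The adjusted p for EIF4E was 0.0699 without vector input replicate 2, 0.0564 without replicate 3 and 0.0845 without vector Cap IP replicate 3. With total counts as library sizes the difference was 0.47 (edgeR adjusted p = 0.364). CMTR1 fell by 1.84 ± 0.37 (edgeR adjusted p = 7.24e-04). PCIF1, which overlaps a gene on the opposite strand, rose by 0.90 ± 0.30 (edgeR adjusted p = 0.0209). For PCIF1 the adjusted p was 0.0678 without vector input replicate 1, 0.0864 without replicate 2 and 0.108 without vector Cap IP replicate 3. RNMT stood at -0.53 and FAM103A1 at 0.27, and neither passed.

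In vector cells 4921 genes passed by edgeR, 2308 higher and 2613 lower in Cap IP, and 5988 had an unadjusted p under 0.05. DESeq2 called 4808, of which 4243 were among the 4921. With the culture as a block 6041 passed, 2886 higher and 3155 lower, and 4518 of the 4921 were among them. In 49.9% of genes the groups did not overlap, where chance gives 10%. The split depended on the scaling. With total counts as library sizes, which moved the median of all genes by -0.74, 738 genes were higher and 5013 lower. With library sizes from the 13 mitochondrial mRNAs, which moved it by 1.03, 2904 were higher and 552 lower. Simulated changes of 4-fold were called in 63% of cases in this comparison. The simulation changed 200 genes, far fewer than were called here, which makes the adjusted threshold harder to pass. The 63% therefore does not apply to the real comparison.

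Of the lists, 6 stood apart in vector cells by camera, and with an estimated correlation the list of RNA polymerase III transcripts did. The 6 uncapped small RNAs had a median of -7.53, with 5 lower over all genes and 6 adjusted over the list alone (camera adjusted p = 4.40e-14, and adjusted p = 0.0403 with an estimated correlation). The 11 intron-encoded snoRNAs and scaRNAs had a median of -4.50, or -3.21 with the 3 members at 0 counts in a group set to their bound. Of them 10 passed as lower, over all genes and adjusted over the list alone (camera adjusted p = 2.48e-05, and adjusted p = 0.687 with an estimated correlation). The 13 mitochondrial mRNAs had a median of -1.17, with 6 lower over all genes and 7 adjusted over the list alone (camera adjusted p = 8.24e-04, and adjusted p = 0.896 with an estimated correlation). MT-CO1 changed by -3.23 ± 0.34, MT-CO2 by -3.47 and MT-CO3 by -2.70. The 32 extracellular matrix genes had a median of -1.37 and 18 were lower, as many adjusted over the list alone (camera adjusted p = 3.44e-04, and adjusted p = 0.687 with an estimated correlation). The microfibril gene FBN2 changed by -2.69, the collagen gene COL1A1 by -1.91 and the laminin gene LAMC1 by -1.92.

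The 86 TOP mRNAs had a median of 0.62 in vector cells under TMM scaling and of -0.13 with total counts as library sizes. Of them 28 were higher and EEF2 was lower, against 25 and EEF2 adjusted over the list alone (camera adjusted p = 9.43e-07, and adjusted p = 0.896 with an estimated correlation). The ribosomal protein genes RPS25, RPL26 and RPS28 rose by 1.70, 1.44 and 1.24, and FAU rose by 1.32. The 31 replication-dependent histones had a median of 0.88, and of 0.09 with total counts, where 2 were higher and 1 lower. Under TMM scaling 12 were higher over all genes and 13 adjusted over the list alone (camera adjusted p = 3.04e-04, and adjusted p = 0.896 with an estimated correlation). HIST1H4I rose by 2.12 and HIST1H1E by 1.72, although reads of such near-identical copies may be split between genes in counting. The 30 long noncoding RNAs had a median of 0.54, and of -0.19 with total counts as library sizes (camera adjusted p = 0.0653). LINC00511 rose by 1.55 and OIP5-AS1 by 1.70, and KCNQ1OT1, with 51 counts in input and 2 in Cap IP, had a log2 ratio of -3.97 (95% counting interval -7.05 to -2.04). The 26 reported eIF4E targets had a median of 0.04, and of -0.68 with total counts (camera adjusted p = 0.697). Among them FGF2, a growth factor gene with exons opposite to NUDT6, rose by 1.84 ± 0.33 (edgeR adjusted p = 2.34e-04) and RANBP1, a transport factor gene, rose by 1.16. Of the other lists, none passed. PRPF8 in the spliceosome list fell by 2.74 ± 0.27 (edgeR adjusted p = 1.18e-06), and EIF4G1 and LARP1 among cap-binding proteins fell by 1.86 and 1.95.

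The third comparison asked the same of eIF4E cells, and the picture was close to that in vector cells. RN7SL1, RN7SK and RMRP were again strongly lower, and TAF5, MCMDC2, TEX9 and SSB were again among the 8 genes with the largest gains. E2F5, NECAB1 and the pseudogene ZNF619P1, also among these, had not been so in vector cells. Extracellular matrix genes were lower as a list by camera with its preset correlation, with 18 of 32 members lower and 2 higher, and this was lost with an estimated correlation (adjusted p = 0.549). The long noncoding RNA OIP5-AS1 and the cyclin gene CCNA2 were higher, and the nucleoporin gene NUP214 was lower.

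RN7SL1 changed by -8.74 ± 0.59 on the log2 scale in eIF4E Cap IP against eIF4E input, RN7SK by -8.38 ± 0.57 (edgeR adjusted p = 7.80e-09 for both) and RMRP by -8.19 ± 0.58 (edgeR adjusted p = 1.09e-08). With 0 counts in eIF4E Cap IP, SCARNA10 was at least 24.1-fold lower, RN7SL5P at least 19.2-fold and SCARNA13 and SNORD33 each at least 15.9-fold. FILIP1L, a filamin-interacting gene on chromosome 3, was at least 13.5-fold lower. ZNF619P1 rose by 4.95 ± 0.73 (edgeR adjusted p = 2.79e-05), and TEX9 rose by 4.82. Their eIF4E input means of 0.76 and 1.49 CPM lay near or below the level of 3 counts per library, so these sizes are uncertain. MCMDC2 rose by 4.64 ± 0.53 (edgeR adjusted p = 3.00e-06), SSB by 4.54 and TAF5 by 4.51. E2F5, a cell cycle transcription factor gene opposite to RBIS, rose by 4.32, and NECAB1, a calcium-binding protein gene opposite to C8orf88, rose by 4.23. All 16 genes with the largest changes were called without any 1 of the 6 libraries. EIF4E was higher in Cap IP by 1.00 ± 0.34 (edgeR adjusted p = 0.0211), and its adjusted p was 0.0539 with DESeq2. The edgeR adjusted p for EIF4E was 0.0721 without eIF4E Cap IP replicate 1, 0.0559 without replicate 3, 0.0602 without eIF4E input replicate 2 and 0.0515 without replicate 3. CMTR1 fell by 1.55 ± 0.38 (edgeR adjusted p = 0.00297), and PCIF1 stood at 0.63 ± 0.30 (edgeR adjusted p = 0.0925).

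In eIF4E cells 5625 genes passed by edgeR, 2726 higher and 2899 lower in Cap IP, with 6527 at an unadjusted p under 0.05. DESeq2 called 5445, of which 5030 were among the 5625. With the culture as a block 5651 passed, 2607 higher and 3044 lower, and 4978 of the 5625 were among them. In 54.8% of genes the groups did not overlap, where chance gives 10%. With total counts as library sizes, which moved the median of all genes by -0.85, 1101 were higher and 5866 lower. With mitochondrial mRNAs, which moved it by 0.17, 846 were higher and 707 lower. Vector and eIF4E cells shared 1911 of the genes called higher, where independent lists would share 504.9, and 1943 of those called lower, where they would share 608.0. No gene was called in opposite directions. Across the 12460 genes, which are not independent replicates, the log2 ratios of the 2 kinds of cells had a Pearson correlation of 0.86 and a Spearman correlation of 0.87.

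**Figure D2:**
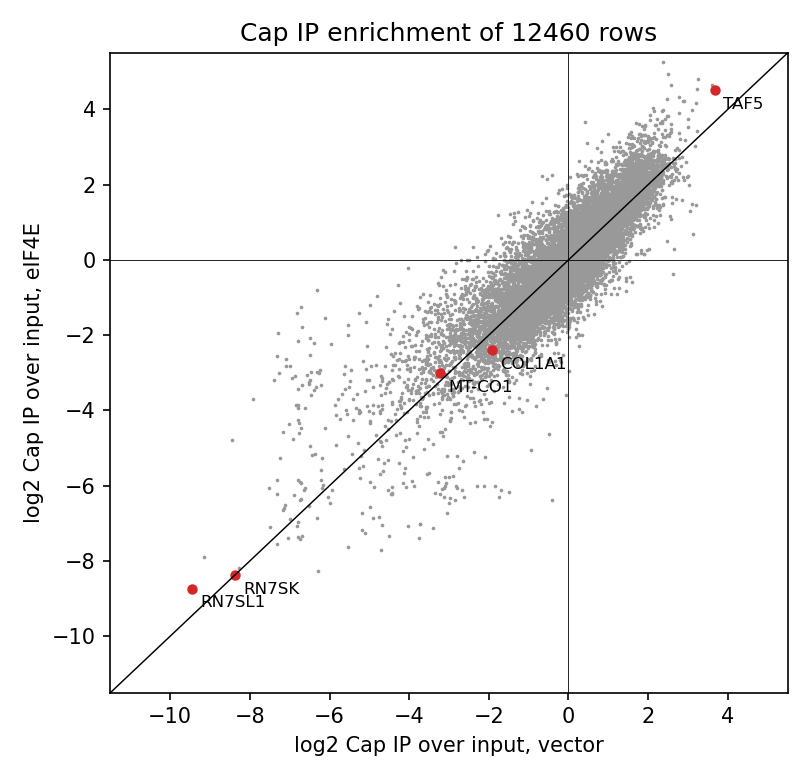
Log2 Cap IP over input of each of the 12460 tested genes in vector cells (horizontal axis) and eIF4E cells (vertical axis), with 5 genes named in red and the line of equal values. Points follow the line (Pearson correlation 0.86), from RN7SL1 at -9.45 and -8.74 to TAF5 at 3.68 and 4.51.

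By camera, 3 lists stood apart in eIF4E cells. The 6 uncapped small RNAs had a median of -7.78 and 5 were lower, as many adjusted over the list alone (camera adjusted p = 3.36e-12, and adjusted p = 0.0430 with an estimated correlation). The 11 snoRNAs and scaRNAs had a median of -6.12, or -3.00 with the 6 members at 0 counts in a group set to their bound (camera adjusted p = 2.05e-05, and adjusted p = 0.549 with an estimated correlation). Of these, 10 passed as lower, over all genes and adjusted over the list alone. The 32 extracellular matrix genes had a median of -1.70, with 18 lower over all genes and 19 adjusted over the list alone (camera adjusted p = 1.12e-04, and adjusted p = 0.549 with an estimated correlation). COL1A1 changed by -2.39, the tenascin gene TNC by -2.64 and FBN2 by -2.34, and 2 members, THBS2 and ITGB1, were higher. TOP mRNAs had a median of 0.25, and of -0.61 with total counts (camera adjusted p = 0.177). Of them 8 were higher and EEF2 was lower, and adjusted over the list alone RPL26, RPS25 and NPM1 were higher. With total counts 0 were higher and 35 lower. The histones had a median of 0.56, and of -0.30 with total counts (camera adjusted p = 0.0649). The mitochondrial mRNAs had a median of -0.46 (camera adjusted p = 0.149), and MT-CO1, MT-CO2, MT-CO3 and MT-ATP6 were lower, as adjusted over the list alone. MT-ATP6 was not called without eIF4E Cap IP replicate 2 (edgeR adjusted p = 0.109) or without eIF4E input replicate 3 (0.0561). MT-CO1 changed by -3.02, MT-CO2 by -2.77 and MT-CO3 by -2.15.

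Long noncoding RNAs had a median of 0.75 in eIF4E cells, and of -0.09 with total counts (camera adjusted p = 0.0649). OIP5-AS1 rose by 2.65, LINC01116 by 2.74, the snoRNA host ZFAS1 by 2.06 and FTX by 1.70, each with exons opposite to another gene. Reported eIF4E targets had a median of -0.15, of 0.08 with mitochondrial mRNAs as the scale and of -1.01 with total counts, where 1 was higher and 13 lower (camera adjusted p = 0.973). FGF2, opposite to NUDT6, rose by 2.60 ± 0.34 (edgeR adjusted p = 9.74e-06). BCL2L1 fell by 1.01 ± 0.32 (edgeR adjusted p = 0.0149), and without eIF4E Cap IP replicate 1 or eIF4E input replicate 3 the adjusted p for BCL2L1 was 0.0873 and 0.0641. PRPF8 changed by -2.97, the pyrimidine synthesis gene CAD by -3.40, EIF4G1 by -2.47 and LARP1 by -2.28. CCNA2, opposite to EXOSC9, rose by 3.16 and NUP214 fell by 3.56. The large subunit gene of RNA polymerase II, POLR2A, fell by 2.22, and the hypoxia gene PDK1, opposite to another gene, rose by 2.20.

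The fourth comparison asked whether eIF4E changed the Cap IP enrichment of individual transcripts, as the difference of both log2 ratios (eIF4E minus vector). No gene passed by edgeR, and 51 did, all with a higher enrichment in eIF4E cells, with the culture as a block. The 5 lists of TOP mRNAs, nuclear respiratory chain genes, immediate early genes, RNA polymerase II genes and spliceosome genes lay below the other genes, and the mitochondrial mRNAs lay above them, by camera with its preset correlation. None of the 6 calls held with an estimated correlation (adjusted p = 0.680 for each).

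By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 0 genes of 12460 passed, and the smallest adjusted p was 0.833. At an unadjusted p under 0.05 there were 728 genes, or 5.84%, and DESeq2 called 0. In 16.6% of genes the 3 eIF4E cultures did not overlap the 3 vector cultures, where chance gives 10%. With the culture (title stem) as a block, 51 genes passed, 51 higher and 0 lower in eIF4E cells. The fit without a block was set beforehand as the first choice, with the block as an alternative. Residuals of input and Cap IP correlated at 0.43, 0.27 and 0.44 in vector cultures and at 0.35, 0.08 and 0.11 in eIF4E cultures. Except in eIF4E culture 3, each input correlated best with its own Cap IP among the Cap IP libraries of its kind of cell. Which of the 2 counts holds is therefore open. In the self-test of the fit without a block, 2% of simulated changes of 2-fold and 18% of those of 4-fold were called. EIF4E stood at -0.19 ± 0.49, CMTR1 at 0.29, RNMT at 0.87, PCIF1 at -0.28 and FAM103A1 at -0.24, with edgeR adjusted p of at least 0.884 for these. The genes with the smallest p, none of which passed, were RFFL, a ubiquitin ligase gene opposite to LIG3, at 1.78 ± 0.46, the serotonin receptor pseudogene HTR5BP at 2.05 and the lipid flippase gene ATP8B1, opposite to ATP8B1-AS1, at 2.07. Next were ITFG1-AS1, opposite to ITFG1, at 1.84, RASA1, a Ras regulator gene opposite to CCNH, at 1.91, CDR1 at 1.44, USP3-AS1, opposite to USP3 and FBXL22, at 1.48 and RSPH10B, opposite to CCZ1, at 1.83.

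Among the lists, TOP mRNAs had a median difference of -0.45, with 77 of 86 members negative (camera adjusted p = 1.86e-08). The ribosomal protein genes RPS3, RPL18 and RPS14 stood at -0.82, -0.85 and -0.75. The 26 nuclear respiratory chain genes had a median of -0.36 (camera adjusted p = 0.00695), with NDUFV1 at -1.28 and COX6B1 at -1.12. The 18 immediate early genes had a median of -0.53 (camera adjusted p = 0.0265), with JUN at -0.72 and DUSP1 at -0.94. The medians were -0.33 for RNA polymerase II genes (camera adjusted p = 0.0310) and -0.18 for spliceosome genes (camera adjusted p = 0.0498), with NELFE at -0.71 and PRPF19 at -0.97. The 13 mitochondrial mRNAs had a median of 0.56, with 12 positive (camera adjusted p = 0.0242) and MT-ND3 at 1.30, and a median of -0.06 when they set the scale. No member of any list passed, over all genes or adjusted over the list alone. Per culture, the median log2 Cap IP over input of TOP mRNAs was 0.64, 0.39 and 0.86 in vector cells and 0.44, 0.60 and -0.20 in eIF4E cells (exact permutation p = 0.4, two-sided, where 3 against 3 cannot give less than 0.1). For immediate early genes it was 0.40, -0.07 and 0.38 against -0.20, -0.20 and -0.46, and for spliceosome genes it was 0.22, -0.01 and 0.33 against -0.09, -0.20 and -0.12, without overlap between the cultures (exact permutation p = 0.1 for each). An exact permutation p of 0.1 was also found for S phase, MYC target, p53 target, cholesterol synthesis, osteoblast and snoRNA host genes. Camera called none of these other lists. The cultures overlapped for respiratory chain and RNA polymerase II genes (exact permutation p = 0.2 for each) and for mitochondrial mRNAs (exact permutation p = 0.6). The 26 reported eIF4E targets had a median of -0.22 (camera adjusted p = 0.328). Within them, PIM1 stood at -1.26 and FGF2 at 0.75, and neither passed.

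**Figure D3:**
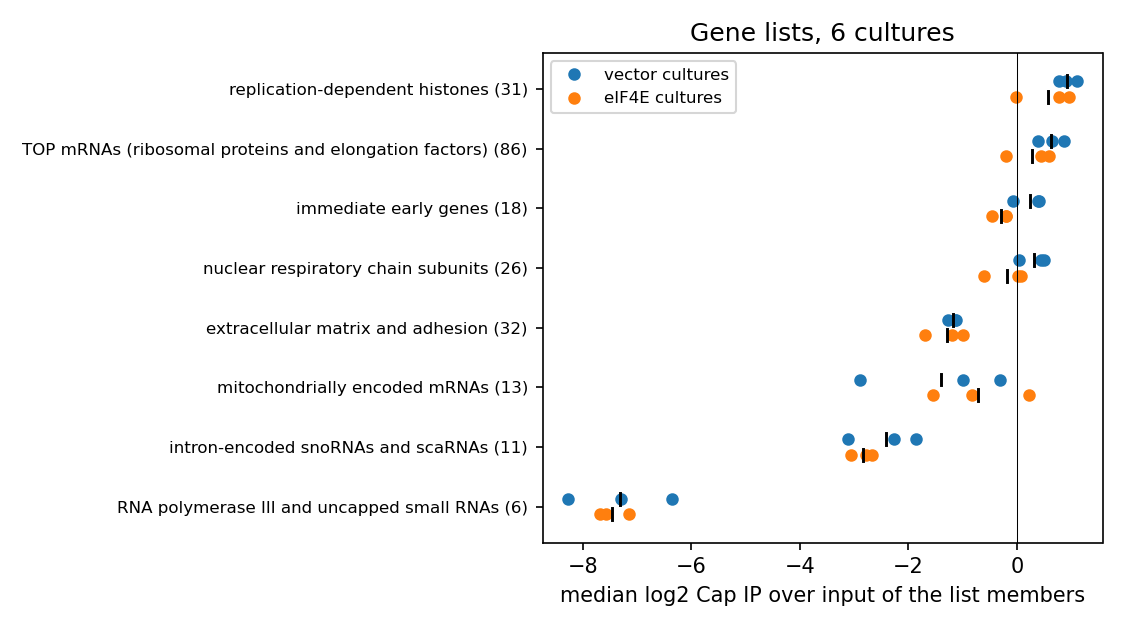
Median log2 Cap IP over input of the tested members of 8 gene lists (their number in brackets) in each of the 3 vector and 3 eIF4E cultures, as points, with the mean of each kind as a bar. Uncapped small RNAs lay lowest in all 6 cultures, and for TOP mRNAs the eIF4E value of -0.20 lay below, and those of 0.44 and 0.60 among, the vector values of 0.39 to 0.86.

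The fifth comparison asked which genes differed between eIF4E and vector cells within Cap IP. Most of the genes that fell had also fallen in input, among them PALM3, SEMA6A-AS1, PAGE2B, GALNT16, ZXDA and ZNF503-AS1. The collagen gene COL27A1 and the pseudogene IMPDH1P4 were called higher in both fractions. The nucleoporin gene NUP153 rose in Cap IP.

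PALM3 had 83 counts in vector Cap IP and 2 in eIF4E Cap IP, a log2 ratio of -5.14 with a 95% counting interval of -8.21 to -3.24 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0232). SEMA6A-AS1 fell by 3.99 ± 0.81 (edgeR adjusted p = 0.0377) and CHD5, a chromatin remodeller gene, by 3.55 ± 0.69 (edgeR adjusted p = 0.0291). The eIF4E Cap IP means of SEMA6A-AS1 and CHD5, 1.31 and 1.33 CPM, lay below the level of 3 counts per library, so these sizes are uncertain. PAGE2B changed by -2.59, the smooth muscle calponin gene CNN1 by -2.39, the glycosyltransferase gene GALNT16, opposite to an unnamed gene, by -2.35, the zinc finger gene ZXDA by -2.33 and ZNF503-AS1, opposite to HMGA1P5, by -1.88. IMPDH1P4 rose by 2.58 ± 0.46, COL27A1 rose from 3.39 to 19.5 CPM, and ZSCAN5A, a zinc finger gene opposite to ZNF542P, rose by 1.92 ± 0.36 (edgeR adjusted p = 0.0232 for each). NUP153, opposite to NUP153-AS1 on chromosome 6, rose from 34.6 to 167 CPM, by 2.28 ± 0.38 (edgeR adjusted p = 0.0232). CMTR1 stood at -0.16, RNMT at 1.23, PCIF1 at -0.21 and FAM103A1 at -0.13, and none of them passed.

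In all, 28 genes passed within Cap IP by edgeR, 10 higher and 18 lower in eIF4E cells, with 1146 at an unadjusted p under 0.05 (9.20%). DESeq2 called 68, which included 27 of the 28. With the title tag shared by vector and eIF4E libraries as a block, 222 genes passed, 124 higher and 98 lower, and 25 of the 28 were among them. In 13.6% of genes the groups did not overlap, where chance gives 10%. Input and Cap IP shared 2 calls higher, COL27A1 and IMPDH1P4, and 13 lower, where independent lists would share 0.0104 and 0.0766. Their libraries come from the same 6 cultures by title stem, so the overlap is not between independent samples. Without eIF4E Cap IP replicate 1 the balance turned, with 23 genes called, 17 higher and 6 lower. No gene was called by edgeR without eIF4E Cap IP replicate 2. AC006116.24 was the 1 gene called without replicate 3, and it was called with CNN1, ZXDA and CTD-2319I12.2 without vector Cap IP replicate 3. Of the 12 genes given above with their changes, 0 were called without eIF4E Cap IP replicate 2 or without replicate 3, and 2 without vector Cap IP replicate 3. They were 7 without eIF4E Cap IP replicate 1, 8 without vector Cap IP replicate 1 and 6 without replicate 2.

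Within Cap IP, TOP mRNAs had a median change of -0.25, with 77 of 86 members negative (camera adjusted p = 1.49e-04), and RPL23A stood at -0.66. Extracellular matrix genes had a median of -0.52 (camera adjusted p = 1.58e-04). Of them 0 passed over all genes and 5 fell adjusted over the list alone, COL1A1 at -1.05, TNC at -1.31, MMP2 at -1.69, MMP14 at -1.27 and TIMP1. The histones had a median of -0.60 (camera adjusted p = 0.00116), with HIST1H2BN at -1.13 and HIST1H4I at 1.35. None of these 3 list calls held with an estimated correlation (adjusted p = 0.822 for each). HOTAIR stood at -2.19 (edgeR adjusted p = 0.0817) and passed adjusted over its list alone.

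RNA classes were compared as the median log2 Cap IP over input per culture. The 577 long noncoding RNAs lay at 0.72 ± 0.24 (SD, n = 3 cultures) in vector and 0.95 ± 0.19 in eIF4E cells (exact permutation p = 0.2, two-sided). The 9244 protein-coding genes lay at -0.17 ± 0.09 and -0.31 ± 0.04, without overlap between the cultures (exact permutation p = 0.1, the smallest possible here). The cultures overlapped among the 4592 with exons opposite to another gene, with a difference of -0.06, and among the 4652 without, with -0.20 (exact permutation p = 0.2 for each). Among long noncoding RNAs, the 476 with exons opposite to another gene lay at 0.86 in vector and 1.13 in eIF4E cells, and the 101 without lay at -0.17 and -0.10. The 17 snoRNAs and scaRNAs lay at -2.09 ± 0.42 and -2.45 ± 0.18 (exact permutation p = 0.3), and the 10 snRNAs at -0.88 and -0.20 (exact permutation p = 0.2). The 140 processed pseudogenes lay at -1.14 and -0.56 (exact permutation p = 0.3), and their cultures did not overlap among the 46 with opposite exons, with a difference of 0.65, or the 94 without, with 0.74 (exact permutation p = 0.1 for each). The 128 genes of other classes lay at 0.07 and 0.31 (exact permutation p = 0.1). The 10 mitochondrial tRNAs lay at -0.79 ± 0.53 and 0.60 ± 0.90, without overlap (exact permutation p = 0.1). The 2334 genes with names that the annotation did not match lay at 0.46 and 0.84 (exact permutation p = 0.2).

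Exon length, the total of a gene's annotated exon bases with overlapping exons merged, went along with Cap IP uptake. Among the 4652 protein-coding genes without exons opposite to another gene, log2 Cap IP over input had a Spearman correlation with exon length of -0.39 in vector cells and -0.27 in eIF4E cells. From the tenth of genes with the shortest exon length to the tenth with the longest, the median went from 0.57 to -0.97 in vector cells and from 0.10 to -0.96 in eIF4E cells. The genes are not independent replicates, so no p-value is given.

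**Figure D4:**
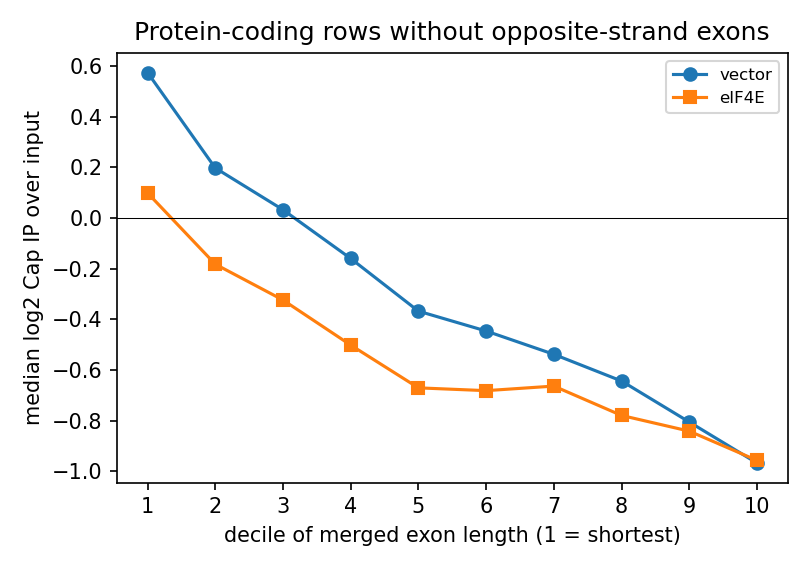
Median log2 Cap IP over input (vertical axis) of protein-coding genes without exons opposite to another gene, in 10 bins of exon length from shortest to longest (horizontal axis), in vector and eIF4E cells. The median fell along the bins, from 0.57 to -0.97 in vector cells and from 0.10 to -0.96 in eIF4E cells.

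Because the scaling removes any shift common to all genes, the enrichment of nuclear mRNAs was also taken relative to the 13 mitochondrial mRNAs, which carry no m7G cap. Nuclear protein-coding genes lay above the mitochondrial mRNAs by 0.85, 2.63 and 0.22 on the log2 scale in the vector cultures, a mean of 1.24 ± 1.25 (SD, n = 3). In the eIF4E cultures the values were -0.57, 1.23 and 0.54, a mean of 0.40 ± 0.91. The difference of -0.83 was smaller than the spread between cultures (exact permutation p = 0.5, two-sided). Without vector culture 2 it was -0.13, and without eIF4E culture 1 it was -0.35.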

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

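The tests of the strand, and the matched random sets for lists other than TOP mRNAs, were chosen only after the result was seen. The p-values of the lists are from camera with its preset correlation, and none passed with an estimated one (adjusted p = 0.680 for each).

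Lists that stood out because the difference in Cap IP enrichment between eIF4E and vector cells passed its own test were 6. The median log2 difference, eIF4E minus vector, was -0.45 for TOP mRNAs, -0.36 for nuclear respiratory chain genes, -0.53 for immediate early genes, -0.33 for RNA polymerase II genes and -0.18 for spliceosome genes. It was 0.56 for mitochondrial mRNAs, and -0.06 when these set the scale. The camera adjusted p was 1.86e-08, 0.00695, 0.0265, 0.0310 and 0.0498 for the first 5 and 0.0242 for mitochondrial mRNAs. No single member passed by edgeR. Against random sets matched on exon length and abundance, RNA polymerase II genes lay at percentile 19.0, respiratory chain genes at 11.9 and spliceosome genes at 48.8, so for these 3 lists length and abundance alone give medians as low. Immediate early genes lay at percentile 0.96.

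For TOP mRNAs, 77 of 86 genes had a lower Cap IP enrichment in eIF4E cells. Exon length and abundance of these genes do not account for all of it, since the median of -0.45 lay at percentile 0.0 of 10000 random sets matched on them, whose median was -0.21 with a 5th to 95th percentile of -0.31 to -0.07. Such sets lack the correlation between ribosomal protein genes, which keeps open whether variation between cultures is enough. A change in the RNAs themselves, which is the biological explanation the design offers, was looked for in 8 genes opposite to TOP genes. These genes, which overlap TOP genes by 111 to 676 bases, could show it only if they hold reads of TOP mRNAs. Whether they do is open. The median of the 8 genes, 0.06, lay at percentile 63.1 of random sets. The 5th to 95th percentile of those sets, -0.43 to 0.39, nearly holds -0.45 itself. The 8 genes, few and of uncertain content, therefore cannot settle whether the RNAs changed.

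Genes opposite to abundant mRNAs often held more reads than the mRNAs' own genes, as VIM-AS1 did with a mean of 17369 counts against 1289 for VIM. Among 59 pairs in which a long noncoding RNA lies for most of its exons opposite to 1 protein-coding gene, the noncoding gene was denser in 78.0% (46 pairs, 95% interval 65.3 to 87.7) and the protein-coding gene in 22.0% (95% interval 12.3 to 34.7), with a median log2 ratio of 3.71. Antisense RNA beside correctly counted sense reads would need over 50% for the second share, and the interval argues against it. Counting on the strand opposite to each gene is a candidate explanation that stays open, since the first share missed the 80% set for it. A first version of the test, on 30 pairs of the fixed lists that share a median of 4.01% of the opposite gene's length, gave 36.7% (95% interval 19.9 to 56.1) and was replaced afterwards.

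Genes with a long total exon length were lower in Cap IP, with a Spearman correlation of -0.39 in vector and -0.27 in eIF4E cells. Abundance alone would need correlations between -0.1 and 0.1 in each of 3 bins of abundance, and the mean of both kinds of cells had -0.20 (95% bootstrap interval -0.25 to -0.15), -0.33 and -0.48, although the lowest bin stood at -0.12 in eIF4E cells and the -0.2 set beforehand was only just passed. Genes opposite to the 5-prime end (20% of the exon length) of a long partner lay above those opposite to its 3-prime end by 1.05 (310 and 365 genes, medians 0.50 and -0.55, permutation p = 1e-05, the smallest that 100000 permutations can give, with genes taken as independent, which they are not). If these genes hold reads of their partners, the lower 95% bound of 0.870 argues against whole-transcript cap loss with length as the only cause. Whether they do is open. Across 1929 genes with 1 protein-coding partner, log2 Cap IP over input had a Spearman correlation of -0.22 with their own exon length and -0.18 with the partner's. Own exon length was not matched between genes at the 5-prime and the 3-prime end. Recovery of 5-prime fragments by the Cap IP is a hypothesis that may explain the trend, and it assumes that these genes hold reads of their partners.

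Each of the 5 comparisons was repeated with the 10 splits of its 6 libraries or cultures into 3 and 3, too few for a share under 0.05. As many genes as in the real split were called in 1 split, the real one, for input (66, highest other 0), for Cap IP against input in vector cells (4921, highest other 0) and in eIF4E cells (5625, highest other 0), and for eIF4E against vector in Cap IP (28, highest other 0). For Cap IP against input, every other split mixed input and Cap IP libraries within a group. That widens the spread within groups so much that 0 calls could be foreseen and lend the real calls no support. For the difference in enrichment all 10 splits gave as many, since the real count was 0, as was the highest other.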

How the results depend on the processing

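Alternatives on opposite-strand exons and on leaving out whole cultures for RNA classes were chosen after seeing the data, and the others beforehand. Where no cause is named, the cause was not tested.

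In input, 66 genes were called, against 137 with the DESeq2 test, 11 with total counts as library sizes, 7 with library sizes from mitochondrial mRNAs, 318 with no low-count filter, 32 with the stricter filter, 18 with only the groups compared and 462 with the title tag as a block over all 12 libraries. Leaving out each library gave 7 to 109. In Cap IP against input, 4921 genes in vector and 5625 in eIF4E cells became 2949 and 3432 with the stricter filter, where 5491 genes were tested, and 1553 in eIF4E cells with mitochondrial mRNAs. Leaving out each library gave 4044 to 4687 and 4560 to 5350. For the difference in enrichment, edgeR called 0 (728 at an unadjusted p under 0.05, DESeq2 0), 3 with no low-count filter (RP11-295I5.4, RP11-681H18.2 and MT-TE) and 51, all higher in eIF4E cells, with the culture as a block, and 0 without each library. In Cap IP, 28 became 68 with DESeq2, 18 with mitochondrial mRNAs, 204 with no filter, 18 with the stricter filter, 6 with only the groups compared, 222 with the tag as a block and 155 with the tag over all 12 libraries. Leaving out each library gave 0 to 30.

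RNA classes kept their direction under the alternatives tried, which were a pseudocount of 0.5, the stricter filter and leaving out single cultures. No other scaling was tried for them. Mitochondrial mRNAs as library sizes moved the median of all genes by -0.86 in the difference, larger than any class difference except for mitochondrial tRNAs. With the stricter filter the difference was 0.40 for other classes and -0.23 for protein-coding genes, and snRNAs gave no value. For snoRNAs it went from -0.36 to -0.56 with that filter and to -0.66 with a pseudocount of 0.5. Their sizes depended on single cultures. The difference went from 0.23 to 0.36 without vector culture 2 and to 0.13 without vector culture 3 for long noncoding RNAs, and from 0.58 to 0.37 for pseudogenes and from 0.38 to 0.25 for unmatched names without vector culture 3. It went from -0.36 to -0.59 without vector culture 1 and to -0.19 without vector culture 3 for snoRNAs. Without eIF4E culture 1 it went to 0.88 for mitochondrial tRNAs, and went from 0.68 to 0.42 for snRNAs. The mitochondrial anchor went from -0.83 to -0.13 without vector culture 2, -1.34 without vector culture 3 and -0.35 without eIF4E culture 1.

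Camera sets a list against the other genes, so its calls cannot show a shift shared by all genes. Of 26 list calls, all kept the direction and threshold of camera with total counts and with blocks, although total counts took the medians in vector cells from 0.62 to -0.13 for TOP mRNAs and from 0.88 to 0.09 for histones. So did 25 calls with DESeq2 size factors and 22 without members that have opposite-strand exons. With an estimated correlation 2 did, those of uncapped small RNAs. With fry, 18 calls no longer passed in one direction and 14 in its mixed form. In genes opposite to 1 member, the direction given by camera was reversed, at p-values far from passing, for TOP mRNAs in input (camera adjusted p = 0.935), in Cap IP (0.753) and in the difference (0.501), and for RNA polymerase II genes in the difference (0.829). The median of these opposite genes was -0.07 for RNA polymerase II in the difference, the same sign as that of the list, and near 0 for TOP mRNAs in Cap IP.

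Of 295 named values, all kept their side of the threshold with DESeq2 size factors, 243 with mitochondrial mRNAs and 263 with total counts. Without the library that raised p most, 257 did. With the culture or the tag as a block 261 did, 16 gained a call and 1 lost it, and some were not tested. No value that passed in either run changed direction. Changes of sign among values that passed in neither run were not counted. With mitochondrial mRNAs the median of all genes moved by 0.28 in input, -0.86 in the difference and -0.57 in Cap IP, and with total counts by -0.11 in the difference. Depth was not varied. It limits which genes can be tested, 12460 of 58684 here.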

Other observations

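All tests in this part were chosen after the data were seen.

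In eIF4E cells, genes whose only opposite-strand partner is a reported eIF4E target had a median log2 Cap IP over input of 1.79 (7 genes, 5 higher and 1 lower, camera adjusted p = 0.00699, and adjusted p = 0.0610 with an estimated correlation). In vector cells the median was 1.08 (camera adjusted p = 0.0668), and the difference had a median of 0.47 (camera adjusted p = 0.0775). Within Cap IP, eIF4E against vector, the median was 0.39 (camera adjusted p = 0.0134, and adjusted p = 0.0819 with an estimated correlation). Genes opposite to snoRNA hosts had a median of 1.69 in eIF4E cells and 1.19 in vector cells (5 genes, in eIF4E cells camera adjusted p = 0.0182, and adjusted p = 0.241 with an estimated correlation) and those opposite to G2/M genes 1.88 and 0.84 (5 genes, with the same p-values in eIF4E cells). Genes opposite to long noncoding RNAs, which include MCMDC2, GAS5-AS1, PRSS12 and LRRC75A from the snoRNA host set and so are no separate finding, had a median of 1.03 in eIF4E cells and 0.36 in vector cells (11 genes, in eIF4E cells camera adjusted p = 0.0384, and adjusted p = 0.142 with an estimated correlation). Genes opposite to TOP genes (8) and to RNA polymerase II genes (7) had medians of 0.39 and 0.42 in eIF4E cells (camera adjusted p = 0.395 and 0.485). Camera set these sets against all other genes, not against genes with opposite-strand exons alone. Among genes with such exons in eIF4E cells, long noncoding RNAs lay at 1.13 and protein-coding genes at -0.13. Whether any median here is particular to its list was not tested.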
